A study of Arabidopsis thaliana with 2 samples.

How the data were processed

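Total RNA of 12-day-old Arabidopsis thaliana seedlings, 1 wild-type and 1 ago1-36 sample, was extracted with TRIzol and made into RNA-seq libraries by the SMART approach, per the labels' protocols. TopHat2 2.0.11 and TAIR10 are named in the submitters' processing notes. The counting tool, its gene annotation, its treatment of reads that match several genes and its use of strand are not given in the sources used here. SMART priming and amplification can favour some transcript regions and lengths, and reads of overlapping genes or near-identical copies cannot be told apart here.

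The authors' deposited table gives, per the file headers, an RPKM value per gene in each library, a GFOLD score and a log2 fold change of ago1-36 over wild-type. RPKM is reads per kilobase of gene and per 1000000 reads as the authors computed it. A GFOLD score is generally understood as a log2 fold change made conservative for low counts, and in the deposited table it was not 0 for any listed gene, with a smallest absolute value of 2.98e-05. The table holds 11957 lines that name a gene. Of these, 291 repeat an earlier gene with the same values and were dropped, which left 11666 genes, and 2 fragment lines that name no gene were not used. The table opens with 45 genes sorted apart from the rest, with no stated meaning. Genes outside the table were not analysed here. Names and coordinates came from the TAIR10.1 reference annotation, where 11556 of the 11666 identifiers matched and 110 did not; the table itself carries no coordinates.

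Whole reads were recovered from the RPKM values together with the log2 fold change of the deposited table, which matched the log2 ratio of reads plus 1 less an offset of 0.176622. Among genes with 1 to 100 reads, 2209 of 2210 (99.95%) came out whole within 0.1, against 71.1% from 100 to 300 reads and 15.0% from 300 to 1000. Larger read numbers are therefore estimates rounded to whole reads. Rounding of the deposited digits may limit recovery there, which was not tested. Reads could not be recovered for 14 genes. The totals of the libraries stood in a ratio of 0.994 (ago1-36 over wild-type), and set against annotated exon lengths they came to about 13680000 and 13600000 reads, from the most frequent value over 9039 genes (416 at that value). Exact Clopper-Pearson intervals at the 95% level on the recovered reads are given for folds. PCR reads without molecular identifiers are not independent molecules, so these intervals and the floor of 3 reads per library cover counting error only.

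The main measure was log2 of ago1-36 RPKM plus 1 over wild-type RPKM plus 1, which understates differences of low genes. Folds printed for single genes are plain RPKM ratios. A gene was kept at 1 RPKM or more in at least 1 library and counted as higher or lower at 2-fold on that scale. With 1 library per genotype no p-value or error between replicates exists. A fold against a library at 0 reads was computed against the floor, with the reads of the other library as they stand. The lower limit of the counting interval, which also covers the other library's counting error and lies lower, is given beside it. Each gene list's median was ranked among 10000 random lists matched in 20 bins of mean expression, for lists with 3 or more kept members.

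Before the data were examined, 349 genes were placed in lists of microRNA targets, trans-acting siRNA genes, family members without the site and processes, to which MIR and organelle genes were added by their names. The measure, the thresholds and the alternatives were fixed then too: pseudocounts of 0.1 and 0.5, no filter, a filter of 5 RPKM, and 3 rescalings, by the median of ratios, to a sum of 1000000, and to that sum without organelle genes and the 50 most abundant genes. List members contradicted by the reference names were left out (TAS3C and HSP17.7). The rule for named genes was also fixed: AGO1; the highest and lowest member of each microRNA target list; the 2 members of each other list with the largest absolute ratio; and the 10 highest and 10 lowest genes at 5 RPKM or more in at least 1 library. Other genes printed in the text (among them CSD2, CCS, NF-YA2, SPL4, SPL11, SPL13B, AGO3, ARF3, ARF4, ARF6, KN, TCP4 and AT4G22513, and those of the closing observations) were chosen after their values were seen. Added after the data were seen were the log2 fold change of the authors' deposited table, its GFOLD score, and leaving out genes that overlap another listed gene.

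The steps were tested on simulated libraries of 11652 genes drawn from the means of both libraries. For ago1-36 against wild-type, differences were simulated among genes with at least 100 expected reads. Of these, 100 of 100 at 4-fold and 98 of 100 at 3-fold were called at 2-fold. Of 10960 unaltered kept genes at any depth, 6 were called. The simulation held counting error only, without variation between samples or from amplification. These rates therefore do not describe false calls between the 2 real libraries. In a step over 11160 kept genes, random lists without any difference fell in the outer 5% of matched lists in 11 of 200 cases. Computation used Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.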

Results

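RNA-seq was carried out on 12-day-old Arabidopsis thaliana seedlings of the wild type and of ago1-36, a mutant line of ARGONAUTE1 (AGO1), the protein that carries microRNAs to their target transcripts. Each genotype was represented by 1 library, with about 13680000 reads for the wild type and 13600000 for ago1-36. No difference therefore has a replicate check, and higher or lower always refers to these 2 libraries. The comparison asked which transcripts, known microRNA targets among them, had different levels in the mutant. Expression was read as RPKM for 11666 listed genes, of which 11373 reached an RPKM of 1 in at least 1 library and were kept. Genes with slightly higher RPKM in ago1-36, which lie near 0 on the shifted log2 scale of the authors' deposited table, were scarce. Only 38 kept genes had a log2 ratio from 0.1 to 0.3, against 1417 from -0.4 to -0.2 and 1140 from 0.5 to 0.7. No listed gene had a GFOLD score of 0, and whether genes with that score were left out is not stated. Every count, share, median and percentile therefore describes the listed genes and not all expressed genes. Unlisted genes were not analysed here.

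AGO1 (AT1G48410), the mutated gene, had 48.6 RPKM in the wild-type library and 5.59 RPKM in the ago1-36 library. It was 8.70-fold lower in ago1-36 (95% counting interval 7.65 to 9.89, from 2350 and 269 reads), which goes with the labels. AGO1 spans chromosome 1 from 17885633 to 17892632 in the TAIR10.1 annotation. Across the kept genes, 2228 (19.6%) were at least 2-fold higher in the ago1-36 library and 953 (8.38%) were at least 2-fold lower, on the scale of RPKM plus 1. Differences of 4-fold or more were counted for 698 higher and 163 lower genes, and of 16-fold or more for 72 higher and 11 lower genes. Higher genes made up 70.0% of the 2-fold differences. The log2 fold changes in the authors' deposited table are shifted by -0.185 from the log2 RPKM ratio, and the median of all kept genes was -0.04 on the RPKM scale and -0.23 on theirs. By the log2 fold changes of the authors' deposited table, 2249 genes were higher and 1791 lower, a share of 55.7% higher. Values below are on the RPKM scale.

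The fixed lists held 119 known microRNA targets other than AGO1, of which 77 were listed genes and 74 were kept. Of these 74, 56 had a higher value in the ago1-36 library. At least 2-fold higher were 40 (54.1%), against 19.6% of all kept genes. At least 2-fold lower were 2, against 8.38% of all kept genes, and 32 lay between. The listed targets below the filter, LAC2, DMT2 and MYB11, all had fewer reads in ago1-36 (12 and 0, 13 and 0, 15 and 3). Others, among them PXMT1, FAMT and CUC1, reached 1 RPKM in ago1-36 alone and counted as higher. The filter and the added 1 therefore bear on these shares. Unlisted targets were not analysed here, so these shares do not describe all known targets. Examples of the higher targets were SPL3, a promoter of the juvenile-to-adult transition, CSD1 and CSD2, copper/zinc superoxide dismutases, and NF-YA3, a subunit of a CCAAT-binding transcription factor. SPL3 was 38.2-fold higher (95% counting interval 32.9 to 44.8), CSD1 20.8-fold (95% counting interval 17.5 to 25.0), CSD2 15.2-fold (95% counting interval 13.5 to 17.1) and NF-YA3 13.5-fold (95% counting interval 10.2 to 18.1). The median log2 ratio of these targets was 1.16, and 1.17 with the 2 genes at 0 reads in a library set at their bound. That median stood at percentile 100 among 10000 random lists of equal size matched on mean expression. Percentiles here and for the other lists describe these libraries and are not tests.

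**Figure D1:**
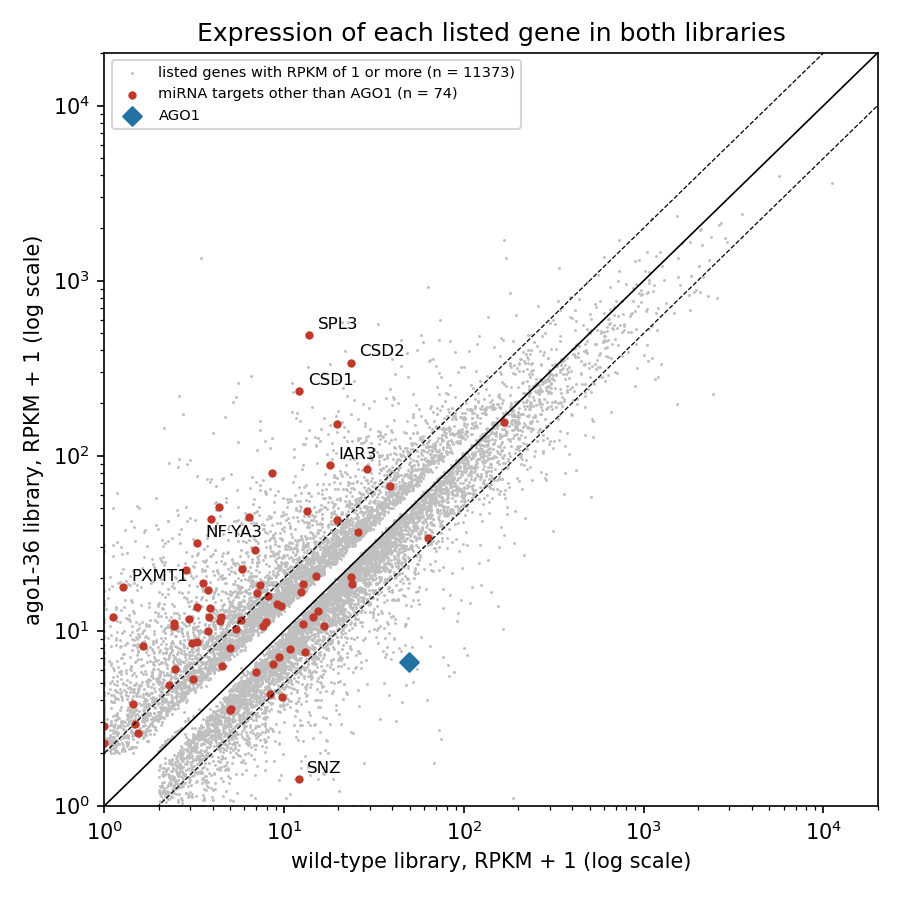
RPKM plus 1 of each kept gene in the wild-type library (x axis, log scale) against the ago1-36 library (y axis, log scale); grey points are the 11373 kept genes, red points the 74 microRNA targets other than AGO1 and the blue diamond AGO1. The solid line marks equal values and the dashed lines 2-fold differences; SPL3, CSD1 and CSD2 lie far above the upper dashed line, AGO1 and SNZ below the lower, and few genes lie just above the solid line, near a log2 ratio of 0.2.

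The SQUAMOSA promoter-binding-like (SPL) genes targeted by miR156 and miR157 set the timing of shoot maturation. All 11 were kept and all had a higher RPKM in the ago1-36 library, 9 of them by at least 2-fold, with a median log2 ratio of 2.12 (percentile 100). SPL3 had 12.7 RPKM in wild-type and 487 RPKM in ago1-36, and SPL13B had 3.32 and 50.2 RPKM. SPL4 was 10.5-fold higher, while SPL6 (4.36 and 9.17 RPKM, log2 ratio 0.92) and SPL11 (log2 ratio 0.96) fell short of the 2-fold mark on the scale with 1 added. SPL3 overlaps the listed gene AT2G33815, and SPL13A and SPL13B are near-identical copies, so reads of these genes may be counted for more than 1 gene and their values are uncertain.

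The miR398 targets CSD1, CSD2 and CCS, the copper chaperone that loads these dismutases, were 3 of 3 at least 2-fold higher, with a median of 3.86 (percentile 99.87). CCS had 18.7 RPKM in wild-type and 151 RPKM in ago1-36. Among NF-YA subunits targeted by miR169, 4 of 5 kept members were at least 2-fold higher (median 1.3, percentile 97.42, and 2.06 under a filter of 5 RPKM or without overlapping genes), led by NF-YA3 and by NF-YA2 at 5.39 and 43.9 RPKM. Growth-regulating factors, which promote leaf cell proliferation and are targeted by miR396, were at least 2-fold higher in 4 of 5 cases (median 2.06, percentile 99.82). Without GRF1 and GRF3, which overlap other listed genes, that median was 1.01. GRF8 was 11.2-fold higher from only 13 wild-type reads (95% counting interval 6.36 to 21.6), and GRF2 had 2.13 and 4.28 RPKM. The miR163 targets, methyltransferases of the SABATH family, were near 0 in wild-type, so that each was kept through its ago1-36 value, and 3 of 3 were at least 2-fold higher (median 3.42 with or without the gene at 0 set at its bound, percentile 99.98, and 4.14 to 5.54 under other pseudocounts and scalings that moved it). PXMT1 had 5 reads in wild-type and 314 in ago1-36 (63.2-fold, 95% counting interval 26.8 to 196), and AT3G44870, with 0 and 30 reads, was at least 10.1-fold higher against the floor of 3 reads (95% counting lower limit 7.69).

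Pentatricopeptide repeat genes targeted by miR161, whose products act on organelle transcripts, were at least 2-fold higher in 7 of 9 cases (median 1.41, percentile 99.86). AT1G63150 was 5.45-fold higher and AT1G63080 had 0.528 and 1.59 RPKM, and these near-identical copies can share reads. IAR3, an enzyme that frees auxin from its amino acid conjugates, was 5.16-fold higher (95% counting interval 4.63 to 5.77), whereas its fellow miR167 targets ARF8 (14.1 and 19.6 RPKM) and ARF6 stayed under 2-fold (list median 0.54, percentile 71.82). ARF17, an auxin response factor targeted by miR160, was 5.77-fold higher, and ARF10 had 7.62 RPKM in wild-type and 5.42 RPKM in ago1-36 (list median 0.49, percentile 57.73). AGO2, an antiviral Argonaute targeted by miR403, was 2.95-fold higher (95% counting interval 2.77 to 3.15), and with AGO3 and AGO1 its list had 2 higher members and 1 lower (median 1.40, percentile 96.3). That median turned to -0.69 under a filter of 5 RPKM, which removes AGO3. ARPN, the plantacyanin targeted by miR408, was 11.4-fold higher, while the laccase LAC4 had 12.1 and 6.55 RPKM (list median 0.64, 1 of 3 higher, percentile 67.9). Among targets of less conserved microRNAs, the MADS-box gene AGL16 was 4.71-fold higher and the chromomethylase CMT3 had 4.07 and 2.58 RPKM, in a list with 2 of 3 kept members higher (median 1.40, percentile 94.95). Without the filter on low values that list's median was -0.27, and scaled without organelle genes and the 50 most abundant genes it was 0.43.

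Other target families had smaller, mixed or opposite differences. The APETALA2-like floral repressors targeted by miR172 were all 4 lower in ago1-36, 2 of them at least 2-fold (median -1.05, percentile 0.57). SNZ was 26.7-fold lower (95% counting interval 12.7 to 67.3, 188 and 7 reads), and TOE2 had 8.40 RPKM in wild-type and 6.08 RPKM in ago1-36. Class III HD-ZIP genes of the miR165 and miR166 list, which specify the upper leaf side, all stayed under 2-fold (median -0.36, percentile 19.94), from PHB at 15.6 and 9.65 RPKM to REV at 3.53 and 5.25 RPKM. The miR319 targets TCP2, TCP4 and TCP10, regulators of leaf growth, had a median of -0.21 (percentile 31.38), with TCP2 at 6.90 and 10.2 RPKM and TCP10 at 22.6 and 19.2 RPKM. Members of the miR164 list, NAC transcription factors, went both ways: NAC1 was 2.73-fold higher and CUC1 at least 5.70-fold higher against the floor (95% counting lower limit 4.15), while NAC080 had 7.34 RPKM in wild-type and 3.35 in ago1-36 (list median 0.35, 0.41 with CUC1 at its bound, percentile 60.15). Without genes that overlap another listed gene, the miR164 median was -0.50. APS4, an ATP sulfurylase targeted by miR395, was 2.24-fold higher and APS1 had 167 and 155 RPKM (list median 0.53, percentile 72.05). The auxin receptors AFB2 and AFB3 of miR393 had a median of -0.32, and the single listed members of 4 further lists were DCL1 of miR162 (0.42), LCR of miR394 (0.52), PHO2 of miR399 (0.78) and HAM3 of miR171 (-0.26), each as a log2 ratio under 2-fold. The 8 members of the miR159 list, MYB transcription factor genes, were not analysed here.

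**Figure D2:**
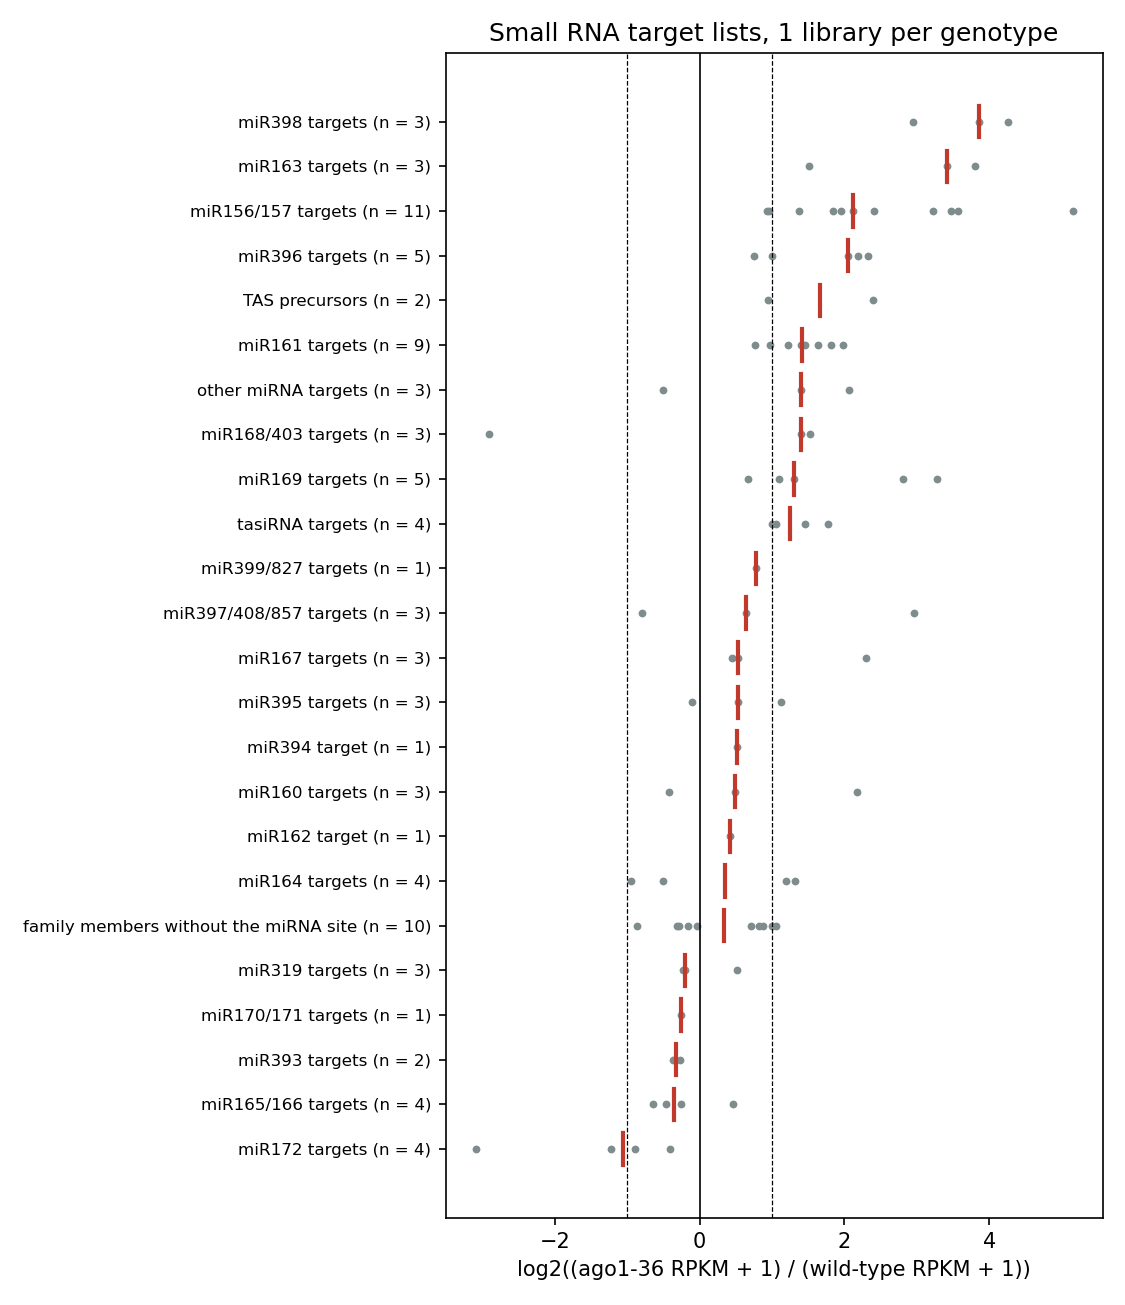
Log2 ratio of ago1-36 over wild-type RPKM, each with 1 added (x axis), for the kept members of each small RNA list (rows); grey points are genes, red bars list medians, dashed lines 2-fold differences, with 1 library per genotype. The miR398 and miR163 lists have the highest medians and the miR172 list, at -1.05, the lowest.

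Of the 7 trans-acting siRNA precursors, which microRNAs guide into small RNA production, 2 were kept and 1 was at least 2-fold higher on the scale with 1 added. TAS1C was 6.95-fold higher (95% counting interval 4.84 to 10.3, uncertain because it overlaps the listed gene AT2G39670) and TAS2 1.99-fold (log2 ratio 0.94, list median 1.67, and 0.94 without TAS1C). Targets of trans-acting siRNAs, the auxin response factors ARF3 and ARF4 and the heat-tolerance genes HTT1 and HTT2, were 4 of 4 at least 2-fold higher (median 1.25, percentile 96.96), with HTT2 at 18.0 and 51.2 RPKM and HTT1 at 4 and 53 reads. SPL, GRF, NF-YA and ARF members without the microRNA site were compared with their targeted relatives. Of 10 kept members, SPL14 alone was at least 2-fold higher on the scale with 1 added, while the plain RPKM ratios of SPL14, SPL8 and GRF5 were 2.12, 2.5 and 2.93. The median was 0.34 (percentile 64.49), which turned to -0.10 under a filter of 5 RPKM. Within the SPL family the median was 2.12 for 11 targeted members and 0.77 for 6 without the site, and within NF-YA 1.3 for 5 and -0.45 for 2. Other small RNA machinery had a median of 0.16 (percentile 48.7), which was -0.13 under that filter, and SGS3, a cofactor of siRNA production, was its only member of 8 past 2-fold on the scale with 1 added, while the plain RPKM ratios of SGS3 and SDN1 were 2.73 and 2.36. Of 8 listed MIR genes, the precursors of microRNAs, 3 were at least 2-fold lower (median -0.61, percentile 2.09). MIR850 had 28.5 and 8.99 RPKM and MIR863 22 and 5 reads, and both overlap the listed gene AT4G13495.

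Photosynthesis genes, markers of leaf mesophyll, were lower in the ago1-36 library in 21 of 21 cases, 13 of them by at least 2-fold (median -1.07, percentile 0). RBCS2B, a small subunit of Rubisco, had 1253 RPKM in wild-type and 331 RPKM in ago1-36, and LHCB1.2, a light-harvesting protein, had 888 and 251 RPKM, though close copies within both families can share reads. Heat shock genes, which encode protein-folding chaperones and their regulators, were lower in all 8 cases, 7 of them by at least 2-fold (median -2.77, percentile 0, and -3.38 by the authors' deposited table). The small chaperones HSP17.6II and HSP17.4 were 17.8-fold (95% counting interval 14.3 to 22.3) and 14.1-fold (95% counting interval 11.1 to 18.3) lower. Root and root hair genes were lower in 7 of 7 cases, 5 past 2-fold (median -1.39, percentile 0.02), among them the cell wall genes PRP3 (8.69-fold) and LRX1 (11.3-fold). Auxin response genes were lower in 9 of 9 cases, 6 past 2-fold (median -1.09, percentile 0.03, -1.75 with a pseudocount of 0.1 and -1.93 by the authors' deposited table), with the repressor genes IAA3 at 53.0 and 15.7 RPKM and IAA14 at 12.2 and 3.23 RPKM. Flavonoid synthesis genes had a median of -0.90 with 3 of 9 at least 2-fold lower (percentile 0.18), including chalcone synthase, CHS (2.77-fold), and LDOX (3.85-fold). Leaf polarity genes had 2 of 7 at least 2-fold lower (median -0.86, percentile 0.42), namely the YABBY genes YAB5, 17.5-fold from 141 and 8 reads, and FIL, 3.01-fold. Shoot meristem genes had a median of -0.82 (percentile 8.06), with KNAT1 2.85-fold lower and KNAT2 at 0.267 and 1.45 RPKM. The cell division genes CYCB1;2, CYCB1;4 and KN, which act at mitosis, were lower by under 2-fold on the scale with 1 added (median -0.83, percentile 3.16). By plain RPKM ratio CYCB1;4 was 2.21-fold lower, and the list median was -1.14 by the authors' deposited table.

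Jasmonate genes, which respond to wounding and insect attack, were at least 2-fold higher in 10 of 10 cases (median 3.14, unaltered with the gene at 0 at its bound, percentile 100). The repressor genes JAZ5 and JAZ1 were 44.0-fold (95% counting interval 33.0 to 60.1) and 22.5-fold (95% counting interval 19.7 to 26.0) higher. Salicylate and defence genes were at least 2-fold higher in 8 of 11 cases (median 1.3, percentile 99.93, and 1.97 with a pseudocount of 0.1). PR1, a marker of salicylate defence, had 1.54 and 48.2 RPKM, and WRKY33, a regulator of immunity to fungi, had 15.7 and 295 RPKM and overlaps the listed gene AT2G38480. Seed and embryo transcripts were at least 2-fold higher in 8 of 8 cases, from wild-type values near 0 (median 2.22, 3.71 with the 5 genes at 0 set at their bound, percentile 100, and 2.96 to 5.22 under the settings that moved it). Each of these 8 reached the filter of 1 RPKM in ago1-36 alone, so the filter itself fixed their direction and bears on the count and percentile, and the other 6 list members were not analysed here. The seed storage proteins CRC and CRA1 had 3 and 6 reads in wild-type and 630 and 645 in ago1-36, at 25.8 and 26.5 RPKM (211-fold for CRC, 95% counting interval 72.0 to 1027). Phosphate starvation genes were at least 2-fold higher in 4 of 7 cases (median 1.25, percentile 99.65), with the non-coding RNAs IPS1 at 3 and 304 reads and AT4 at 22.3 and 94.2 RPKM. Sulfate starvation genes stayed under 2-fold (median -0.29, percentile 22.95), for example LSU2 at 29.5 and 19.7 RPKM and APR1 at 128 and 99.4 RPKM. Flowering genes had a median of 0.32 (percentile 60.08), which turned to -0.17 when libraries were scaled without organelle genes and the 50 most abundant genes and to -0.10 under a filter of 5 RPKM or none, with FUL, a promoter of flowering, 6.52-fold higher and SEP4 at 6.86 and 3.32 RPKM. Reference genes for quantitative PCR stayed under 2-fold (median 0.12, and -0.06 on the scale of the authors' deposited table, percentile 74.04), with TIP41L at 39.4 and 62.9 RPKM and UBC9 at 47.8 and 74.5 RPKM. Organelle genes had a median of -0.20 (percentile 12.97) with 2 of 57 at least 2-fold higher and 1 lower, and held 2.85% of summed RPKM in wild-type and 2.70% in ago1-36. ATCG00900 had 1095 and 2259 RPKM and ATMG00285 18 and 3 reads.

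**Figure D3:**
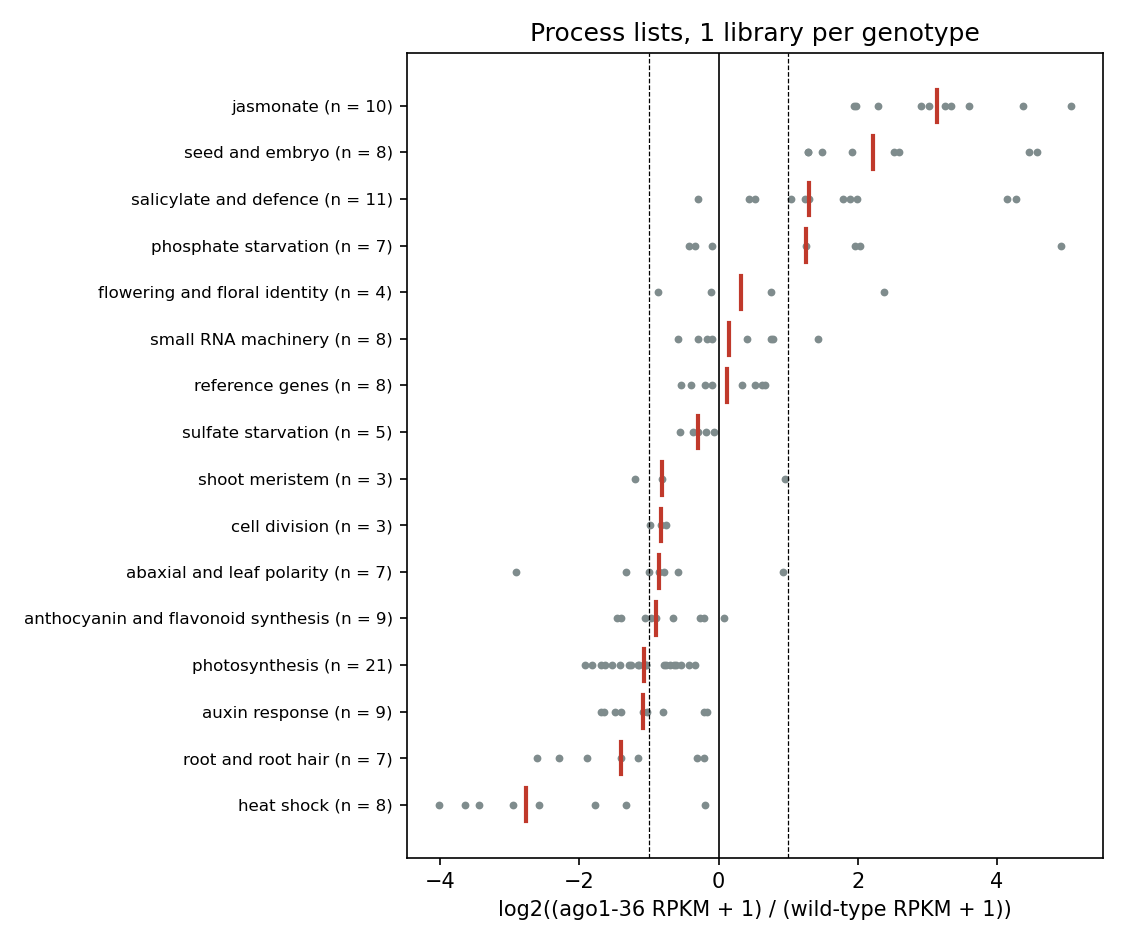
Log2 ratio of ago1-36 over wild-type RPKM, each with 1 added (x axis), for the kept members of each process list (rows); grey points are genes, red bars list medians, dashed lines 2-fold differences, with 1 library per genotype. On this scale, which shrinks the ratios of low genes such as those of the seed list, jasmonate genes have a median of 3.14, seed genes of 2.22 and heat shock genes of -2.77.

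On the scale with 1 added, the 10 highest ratios among genes with 5 RPKM or more in at least 1 library belonged to BAM5, RRTF1, AT3G02840, MYB15, TDR1, AT4G29780, MAPKKK21, TI1, WRKY40 and SAG13. By plain RPKM ratio the ranking differs, for example with CRC at 211-fold above SAG13 at 70.0-fold. BAM5, a beta-amylase, had 2.44 RPKM in wild-type and 1347 RPKM in ago1-36 (552-fold, 95% counting interval 434 to 712). RRTF1, a redox-responsive transcription factor, had 1.58 and 217 RPKM, MYB15 had 1.75 and 173 RPKM, and WRKY40 had 4.41 and 215 RPKM. MAPKKK21 rested on 2 wild-type reads and TDR1 on 1, against 894 and 342 in ago1-36. The 10 lowest ratios on the scale with 1 added belonged to AT4G22485, AT4G22505, RGF9, SAG29, AT1G62510, AT4G22490, AT2G01422, AT4G22510, AT1G66100 and AT4G22517. By plain RPKM ratio AT4G22513, at 7.60 RPKM in wild-type and 0 in ago1-36, would rank below SAG29. Against the floor it was at least 19.2-fold lower, from 58 wild-type reads, so its order against SAG29 is not settled. RGF9, a root meristem growth factor peptide, was 90.8-fold lower (95% counting interval 41.4 to 249) and the sugar transporter gene SAG29 51.8-fold lower (95% counting interval 34.9 to 80.4). AT4G22485 had 5014 reads in wild-type and 3 in ago1-36 (95% counting interval of the fold 568 to 8059.8), and AT4G22505, with 1152 and 0 reads, was at least 382-fold lower against the floor (95% counting lower limit 310.0).

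Of these 10 lowest genes, 5 lie side by side on chromosome 4 with AT4G22513, and most of them encode proteins of the lipid-transfer and seed storage albumin family. The run of 6 consecutive listed genes spans 11844506 to 11857417 in the TAIR10.1 annotation, and each of its genes had at most 3 reads in ago1-36. Against the floor, AT4G22490 was at least 73.6-fold lower (95% counting lower limit 59.3), and AT4G22510 and AT4G22517, which overlap and had 119 wild-type reads each, at least 39.4-fold lower (31.6). The family member next to the run, AT4G22470, was higher, with 17 reads in wild-type and 1007 in ago1-36, and on the other side AT4G22520 had 29 and 6 reads.

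**Figure D4:**
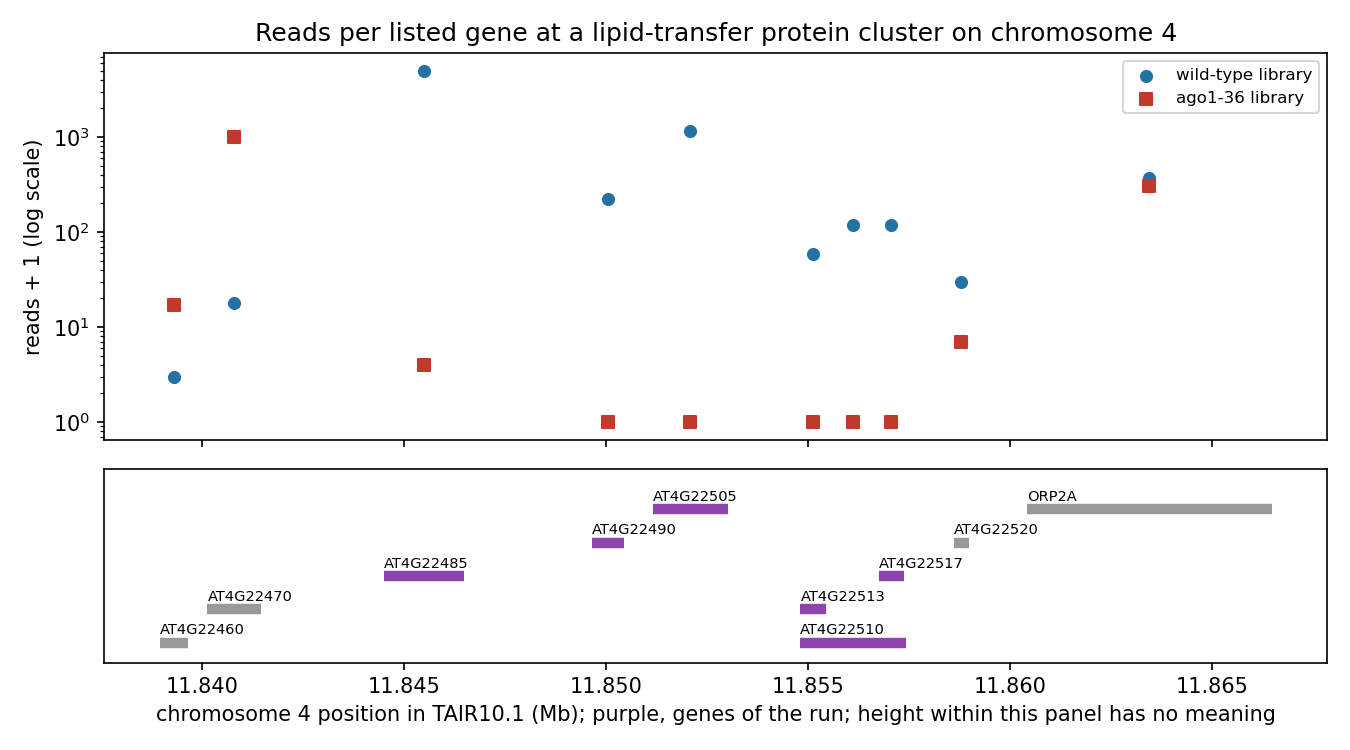
Reads plus 1 per listed gene (upper panel, log scale) in the wild-type library (blue circles) and the ago1-36 library (red squares) along chromosome 4 in Mb of TAIR10.1, with gene spans below (purple, the run of 6 genes; grey, its neighbours). The purple genes had 58 to 5014 reads in wild-type and 0 to 3 in ago1-36.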

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

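The log2 fold change and GFOLD score of the authors' deposited table, and leaving out genes that overlap another listed gene, were alternatives chosen after the data were seen. Of the 49 main values, rescaling by the median of ratios moved 0 beyond 1.5 times or to the other sign, and the cause of the moves below was not tested except where given. The depth of about 13680000 and 13600000 reads leaves genes with few wild-type reads, such as those of the seed and miR163 lists, with wide counting intervals, and a pseudocount weighs most on these by construction. AGO1 was at -3.30 by the log2 fold change of the authors' deposited table. The count of higher genes was 1391 by GFOLD and that of lower genes 1791 by log2 fold change, both in the authors' deposited table. Lower microRNA targets numbered 4 when scaled without organelle genes and the 50 most abundant genes and 5 by the authors' deposited table.

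The miR163 median was 5.53 and 4.21 with pseudocounts of 0.1 and 0.5, 4.14 scaled to a sum of 1000000, 4.29 scaled without organelle and abundant genes, and 5.54 in the authors' deposited table. The seed median under the same settings was 5.22, 3.05, 2.96, 3.15 and 5.15, and 4.46 with a filter of 5 RPKM. That of the less conserved microRNAs' targets was 0.50 scaled to the sum, 0.43 without abundant genes, 0.78 without overlapping genes and -0.27 with no filter, which adds 2 genes below it. The miR168 and miR403 median was -0.69 with a filter of 5 RPKM, which leaves AGO1 and AGO2. The miR169 median was 2.06 under that filter and also without overlapping genes. Without overlapping genes, medians were -0.50 for miR164, 1.01 for miR396 and 0.94 for trans-acting siRNA precursors, with fewer genes in each. With a pseudocount of 0.1, the defence median was 1.97 and the auxin median -1.75. By the authors' deposited table, the auxin median was -1.93 and the heat shock median -3.38. For the 99 named genes besides AGO1, 507 of 594 values moved less than their counting interval, 87 moved more, and 0 of the genes past 2-fold changed sign. Of 68 such genes past 2-fold, 3 were under it by the authors' deposited table.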

Other observations

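The gene families described here were formed by the letters of the gene symbol before its number. The encoded protein was not checked, so a family can hold unrelated genes. These families were chosen only after the results were seen. So were the tests of depth, of handling or growth and of seed RNA. The tests of the chromosome 4 run by family reads, by a drop of the whole family and by gene order were chosen then too. Of 57 families that share a gene symbol and have 10 or more kept members, WRKY factors, regulators of defence, were at least 2-fold higher in 25 of 36 cases and lower in 0 (median log2 ratio 1.70, percentile 100). Ethylene response factors named ERF were higher in 11 and lower in 2 of 20 cases (median 1.47). Plant U-box ubiquitin ligases (PUB), some of which restrain immunity, were higher in 10 of 15 cases (median 1.39). Cysteine-rich receptor-like kinases (CRK) were higher in 12 and lower in 1 of 18 cases (median 1.16), and tau glutathione transferases (GSTU), detoxifying enzymes, in 9 and 1 of 18 cases (median 0.98). Families wider than 2 lists fixed beforehand had medians nearer 0 than those lists. Heat shock proteins named HSP were lower in 11 of 15 cases (median -1.48, and -2.38 by the authors' deposited table). IAA auxin repressors were lower in 5 of 12 (median -0.54). MAPKKK kinases, which act in signalling cascades, were higher in 7 of 10 cases (median 1.38). MYB factors were higher in 18 and lower in 4 of 39 cases (median 0.82), and NAC factors in 15 and 1 of 34 (median 0.61). CIPK kinases, which act in calcium signalling, were higher in 2 and lower in 1 of 12 cases (median -0.19), and ATL ubiquitin ligases were higher in 3 of 10 (median -0.18).

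Alpha-expansins (EXPA), which loosen growing cell walls, were at least 2-fold lower in 7 and higher in 1 of 12 cases (median -1.08, percentile 0), with EXPA8 at 15.4 RPKM in wild-type and 0.666 RPKM in ago1-36. Fasciclin-like arabinogalactan proteins (FLA) were lower in 3 of 14 cases and higher in 0 (median -0.70). Genes with the symbol PIP, which plasma membrane aquaporins carry, were lower in 2 of 13 cases and higher in 0 (median -0.60), with PIP1C at 341 and 138 RPKM. Other cell wall families went both ways, with xyloglucan-modifying enzymes (XTH) higher in 7 and lower in 6 of 20 cases (median -0.25) and arabinogalactan proteins (AGP) in 6 and 5 of 17 (median -0.37). Members of these families can share reads with close copies. The deposited table opens with 45 genes sorted apart from the rest with no stated meaning, 33 of which are in the microRNA lists fixed beforehand. Of these 45, 13 were at least 2-fold higher and 1 lower, and as they may have been picked from these libraries they are not independent evidence of a direction.

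The 6 neighbouring genes on chromosome 4 with at most 3 reads in ago1-36 had 58 to 5014 reads in wild-type. The tables argue against a drop of the whole gene family of this size, since of 22 family members elsewhere with 58 or more wild-type reads, 1 (4.55%) dropped by as much as the least fold of the run against the floor of 3 reads, 19.2. A smaller lowering of the family stays open as a contribution (median -0.66 over 38 kept members outside the run, 15 at least 2-fold lower and 10 higher). Reads assigned to another copy stay open too. Members outside the run that gained reads, AT4G22470 among them, gained 53.9% of the reads lost by the 5 family members in the run. Losses of other members were not subtracted from this sum. It cannot tell reads taken over from a member's own higher expression, and it misses reads taken over by members that fell. The sum therefore cannot decide the question. No random order of 11542 genes placed 6 genes with such a drop side by side (0 of 10000 orders, longest run 2). That result decides nothing, since the run was picked because the genes sit together and most of them belong to the same family. AT4G22510 also overlaps AT4G22513 and AT4G22517, so these genes are not independent. A missing or rearranged stretch in the mutant line, or a difference between the parental lines, may account for the run as a hypothesis. RNA alone cannot separate these from silencing.

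Heat shock genes were lower and jasmonate genes higher in ago1-36. The library totals differed by 1.01 times, so depth was nearly equal. RPKM already divides by the library total, so this value does not test depth as a cause of the pattern. Scaled without organelle genes and the 50 most abundant genes, the heat shock median was -2.85 and the jasmonate median 3.17. A rescaling moves all genes of a library by the same factor, so it could hardly undo differences of this size in opposite directions. Reads taken up by a few abundant genes would likewise move the other genes of a library by a common factor, in the same direction. The 50 highest genes held 18.72% of summed RPKM in wild-type and 14.02% in ago1-36, which is not most of it. These values argue against a few abundant genes taking most of the reads as the cause of the opposite differences in these 2 lists. A small shift common to all genes stays open. Handling or growth of the seedlings behind each library stays open, because there was 1 sample per genotype. An effect of the ago1-36 mutation on these genes is therefore an untested hypothesis that cannot be told apart from a difference between the samples.

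Seed storage transcripts were higher in ago1-36, and RNA of seed or embryo tissue in that library is a candidate explanation. Of 24 kept members of the fixed and an added seed list, 17 (70.8%) were at least 2-fold higher, but 17 of the 24 were below 1 RPKM in wild-type and were kept through their ago1-36 values, so the filter largely sets this share and it decides nothing. Of 8 kept members of the added list whose values had not been seen when they were chosen, 2 were at least 2-fold higher. Of the 7 among the 24 with 1 RPKM or more in wild-type, 1 (ECP63) was at least 2-fold higher, and the oleosin OLEO4 and the desiccation gene RD29B were lower. The most abundant of these markers in ago1-36 was RAB18 at 49.6 RPKM, with 27.8 RPKM in wild-type. Seed tissue and expression in seedling tissue cannot be told apart here.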
